A study of Homo sapiens with 2 samples.

How the data were processed

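Total RNA was measured by RNA sequencing in Ramos cells, a Burkitt lymphoma B-cell line. Per the labels, the cells carried lentiviral constructs for a fusion of catalytically dead Cas9 with SID, a repressor peptide derived from MXD1, together with a guide RNA that has no target. The labels describe 1 group of 2 libraries, here called replicate 1 and replicate 2, and no second condition. They do not say whether the replicates are separate cultures, so differences between them may be technical. P-values of single genes cover counting error and those of gene lists compare genes, so none of them measures variation between cultures.

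The deposited values are raw read counts per gene, not normalized, with 1 library per file. Reads were processed with STAR 2.6.0b and HTSeq on GRCh38, per the submitters' processing notes, which as used here give no HTSeq version. The strand setting and the annotation release are not given in the sources used here. Each deposited count file had 60937 rows, of which 58302 were human gene rows, 45 were pseudoautosomal duplicates with 0 counts, 2385 were decoy contigs, 200 were viral sequences and 5 were summary lines. Only the human gene rows entered library sizes and the tests on genes and gene lists; the row named HIV-1 had a binomial test of its own, given in the closing section. The summary line for alignments at several sites held 39.9% of the sum of all lines in each library. A read may enter that line more than once, so the shares given here need not be exact shares of reads. Reads on no counted feature, which need not lie outside genes, made up 33.2% in replicate 1 and 34.1% in replicate 2. In the same order, ambiguous reads made up 0.999% and 0.927%, and unaligned reads 1.30% and 1.33%. Decoy rows held 0.00643% and 0.00603%, and viral rows 0.00304% and 0.00285%.

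Gene symbols, coordinates and exon lengths came from GENCODE 29 on GRCh38, which matched 58039 gene rows. The 263 unmatched rows held 0.0327% and 0.0344% of the counts. CPM was computed per library total of gene rows. TPM was computed from the deposited counts with the combined length of all annotated exons, which was available for 99.6% of the gene rows with any count. Long combined exon lengths understate TPM for genes whose main transcript is short, such as ribosomal proteins. Genes covered by exons of other genes were checked over all genes and over long non-coding genes, at a coverage of at least 99%. Of 1155 genes covered on the same strand 1.82% had any count, against 28.7% of 741 covered only on the other strand and 31.8% of 41396 not covered. Among long non-coding genes the shares were 2.04% of 98, 35.8% of 391 and 21.9% of 8517. Values of 17 list members with at least 50% same-strand overlap are therefore uncertain, and among them EEF1G, IGLC1, RN7SK, RN7SL1, RPPH1, SCARNA2, RNU11, RNU12, HIST1H2AM and HIST1H3D had 0 counts. The others were MEF2B, ELL3, NOP2, PPAN, TERC, SCARNA10 and CYP51A1. Members of near-identical families, such as histones, immunoglobulin segments and ribosomal proteins with pseudogene copies, are uncertain too, because reads placed at several sites were not counted.

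Library scaling used TMM in edgeR 4.0.16 under R 4.3.3, with factors of 0.999 and 1.00, and DESeq2 1.42.0 size factors served as an alternative. No test between conditions was possible. Genes that differed between the libraries were found with a two-sided exact conditional binomial test on genes with at least 10 counts in total, with Benjamini-Hochberg adjustment at 0.05. That test covers counting error only. The level of each of 32 gene lists was the median of log2(TPM + 1) with a pseudocount of 1, set against 10000 random lists of equal size from genes of the same class. Immunoglobulin constant genes were set against protein-coding genes. Shifts of 23 lists between the libraries used members with at least 20 counts in total and 10000 random lists matched on expression in 20 bins. B-cell genes were compared with 7 other lists by a two-sided permutation test with 100000 resamples. Shares of counts carry exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only. An SD of 2 libraries can fall below counting error, as for MYC, HDAC1 and TRAC, and then overstates precision. Python 3.11.15, SciPy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

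The tests were tested on simulated data for the comparison of genes between the libraries. Genes set to change had at least 100 counts in total in the deposited data, so recovery below that count was not simulated. With counting error alone, 15071 genes were tested and 6 unchanged genes were called. Recovery was 46.0% of 50 genes changed 1.25-fold, 80.0% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold. With the estimated biological coefficient of variation of 3.26% added, 15105 genes were tested and 224 unchanged genes were called. Of 200 random lists of 20 genes, 3% passed an unadjusted p of 0.05 in the level test. Those lists came from the same genes as the random lists of the test, so a rate near 0.05 was set by construction. For the shift test, 100 lists of 20 genes were drawn only from genes well above its minimum of 20 counts in total. Of these lists 7% passed, and 94% passed after a log2 shift of -0.1 was added. Lists with low-count members were not simulated for that test, and lists of genes that vary together were simulated for neither test.

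Lists, the tests described above, their alternatives and the rule for named genes were fixed before the data were examined. The checks of strand, GC content, transcript length, viral reads and T cell receptor reads were chosen after counts were seen. The rule took every member of the MYC-MAX network, the 2 highest and the 1 lowest member of each other list with at least 10 counts in both libraries, and the 2 highest of each list of other cell types. It also took the 10 genes with the highest mean CPM, and the 5 genes with the largest ratio in each direction among those called with at least 100 counts in total. XIST and Y-linked genes were not named. Genes named outside the rule, such as BANK1, the genes with overlapping exons and the T cell receptor genes, were chosen after their values were seen. Alternatives covered expression thresholds, scaling, count filters, minimum folds, the unit, the pseudocount, the background, the mean in place of the median, each replicate left out, and mitochondrial genes left out of the total. A correction for GC content was added after the data were seen. CASC21 and CCAT1 matched no row, and RMRP, which has overlapping rows, was not analysed here.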

Results

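RNA sequencing read the transcriptome of Ramos cells carrying constructs for dead Cas9 fused to the MXD1-derived SID repressor and a non-targeting guide RNA. The group held 2 libraries, with 8799681 counts on human genes in replicate 1 and 7221283 in replicate 2. The series title places the work in a study of MYC-driven proliferation. With no second condition, the libraries describe the transcriptome of these transduced cells, and the comparisons are between gene groups and between the libraries.

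Ramos cells transcribed 13302 genes at 1 CPM or more in both libraries, of which 10575 were protein-coding, 1823 long non-coding, 644 pseudogenes, 197 short non-coding and 26 immunoglobulin or T cell receptor segments. The highest gene was the nuclear long non-coding RNA MALAT1 at 5954 ± 313 CPM (SD, n = 2). It was followed by the mitochondrial genes MT-CO1 at 4252 CPM and MT-ND4 at 3484 CPM, and by the immunoglobulin heavy chain gene IGHM at 3350 CPM. ACTB, EEF2, MT-ND5, MT-CO3, SYNE2 and PABPC1 completed the 10 highest genes, which together took 3.43% of counts in replicate 1 (Clopper-Pearson 95% interval 3.41% to 3.44%) and 3.36% in replicate 2 (3.35% to 3.37%). The 6 of them that are not mitochondrial averaged 2.10% of the total without mitochondrial genes.

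MYC, the transcription factor that Burkitt translocations place under immunoglobulin control, was the dominant member of its network at 633 ± 0.407 TPM (SD, n = 2), from 4312 and 3462 counts. That SD lies below counting error, since the log2 ratio between the libraries had a counting SE of 0.033. MYC lies on chromosome 8 from 127735434 to 127741434 on the plus strand of GRCh38. Its obligate partner MAX stood at 74.6 ± 2.90 TPM, so that MYC exceeded MAX 8.49-fold (log2 3.09 ± 0.06, SD, n = 2). MGA and MLX followed at 53.3 and 53.03 TPM, and MLXIP at 41.2 TPM. Below these came MXD4 at 25.1, MNT at 21.2, MXI1 at 20.2 and MXD3 at 13.5 TPM. MXD1, the gene from which the SID peptide derives, had 79 and 72 counts and 5.85 ± 0.520 TPM, 108-fold below MYC (log2 6.76 ± 0.13). These counts do not separate the MXD1 transcript from any reads of the peptide's coding sequence in the construct. MYCL had 11 and 3 counts, MLXIPL 0 and 1, and MYCN 0 and 0, where a count of 0 allows up to 3 counts, or 0.341 and 0.415 CPM. The ratios depend on gene length: in CPM the log2 ratio of MYC was 2.52 over MAX, 1.02 over MGA and 5.68 over MXD1. As a group the 13 members were not called against random protein-coding lists (percentile 88.2, adjusted p = 0.334). With both members and background limited to genes with at least 10 counts in both libraries, 10 members remained and the percentile was 43.2.

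**Figure D1:**
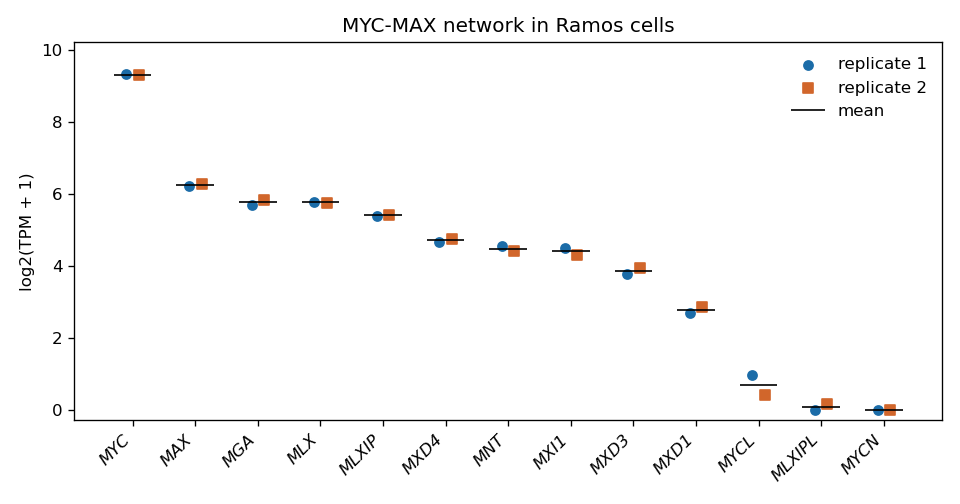
Each point is the log2(TPM + 1) of a MYC-MAX network gene in replicate 1 (circles) or replicate 2 (squares), and each line is the mean of both. MYC lies highest at 633 TPM and MXD1 lies at 5.85 TPM.

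The SIN3-HDAC corepressor, the complex that SID recruits, was expressed in full: all 20 measured members passed 1 CPM in both libraries, with a median of 52.5 TPM. The histone-binding protein RBBP4 stood at 262 ± 4.59 TPM and the deacetylase HDAC1 at 200.1 ± 0.207 TPM (SD, n = 2), while BRMS1L was lowest at 10.9 TPM. The list's median lay at percentile 99.94 of random lists (adjusted p = 0.00345). Against genes with at least 10 counts in both libraries it lay at percentile 91.5 and was not called.

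B-cell genes lay high against random protein-coding lists, with a pan-B-cell median of 193 TPM. The median marker of 6 other lineages was 0 TPM, although 3 of 13 T cell genes passed 1 CPM in both libraries. Of 20 pan-B-cell genes 19 passed 1 CPM in both libraries, led by the B-cell receptor signalling chains CD79A at 982 ± 23.7 TPM and CD79B at 649 ± 35.3 TPM (SD, n = 2), with CR2 at 12.02 TPM, the lowest of those 19. The scaffold gene BANK1, named after its values were seen, had 0 and 0 counts. Germinal centre and Burkitt genes passed in 19 of 21 cases, with ID3 at 1008 TPM and its partner TCF3, a B-lineage transcription factor, at 659 TPM, and LMO2 at 4.15 TPM. Both lists lay at percentile 100 (adjusted p = 0.000533). Plasma cell genes were split: JCHAIN reached 3751 TPM and MZB1 402 TPM, while 3 of 11 members stayed under 1 CPM in at least 1 library, and the list was not called (percentile 97.0, adjusted p = 0.119). By the mean of members it lay at percentile 99.9 and was called. IGHM at 7015 TPM and the lambda chain gene IGLC2 at 5604 TPM led the immunoglobulin constant genes, of which 5 of 16 passed 1 CPM, with IGHG3 at 5.41 TPM.

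Pan-B-cell genes exceeded each of 6 lists of other lineages by 6.55 to 7.03 on the log2(TPM + 1) scale. By a permutation test over genes, which are not independent replicates, adjusted p was 2.8e-05 for T cell, NK cell, myeloid, erythroid and fibroblast lists and 4.67e-05 for epithelial genes. The smallest p that these permutations can give is 2e-05. The difference from plasma cell genes was 1.59 (permutation adjusted p = 0.166). The highest T cell genes were the kinase ZAP70 at 8.28 TPM (95 and 78 counts) and the receptor IL7R at 2.25 TPM (32 and 24 counts). KLRC1 led NK cell genes with 3 and 3 counts and NKG7 had 1 and 0. ITGAM led myeloid genes with 6 and 5 counts and LYZ had 0 and 2. HBB had 2 and 2 counts, ITGA2B 3 and 3, KRT8 2 and 3, KRT18 1 and 0, COL3A1 1 and 0, and COL6A3 1 and 1. The medians of these 6 lists were 0 TPM, a floor at which the level test has little room to call a list below.

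**Figure D2:**
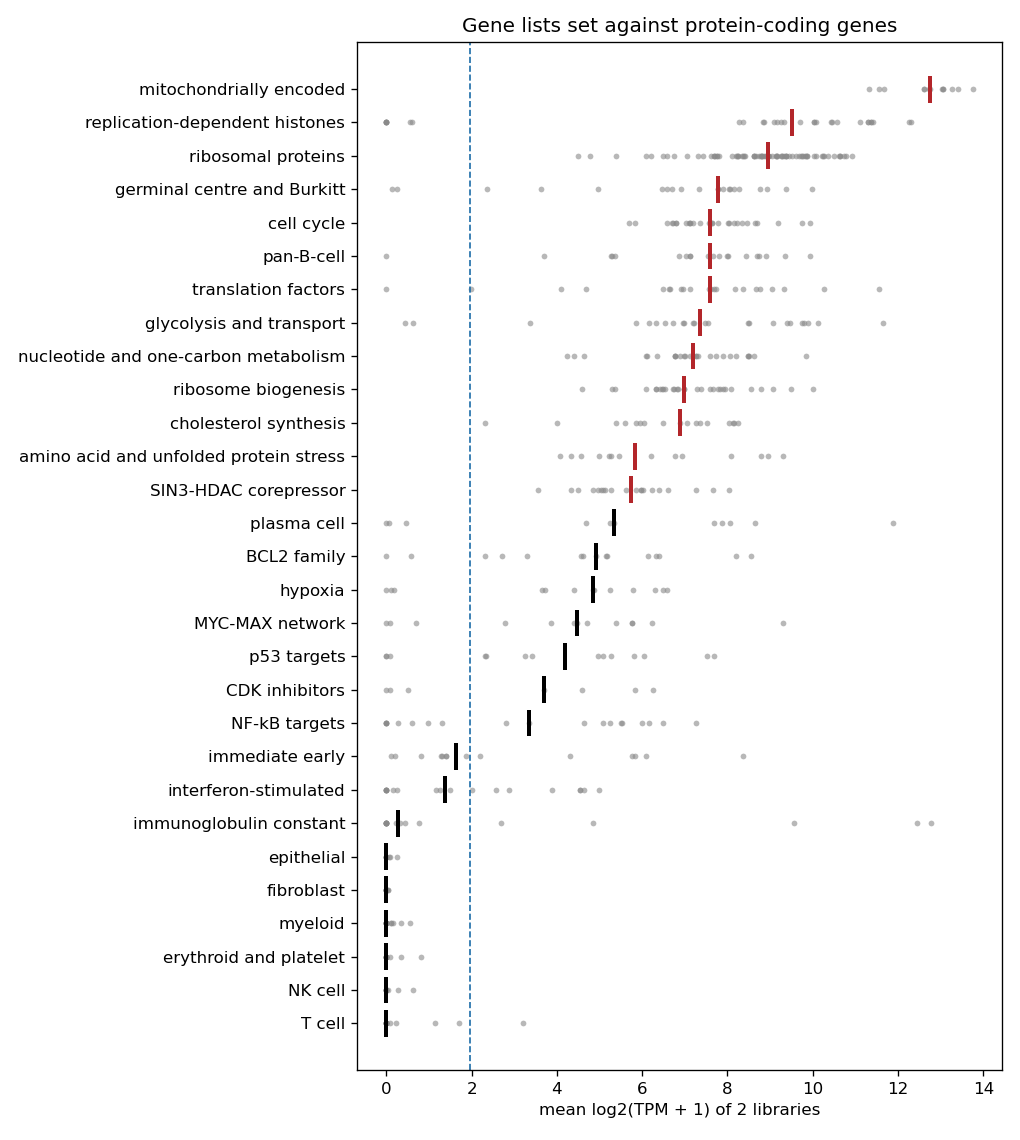
Grey points are list members and thick bars are list medians, as the mean log2(TPM + 1) of both libraries, for 29 lists set against protein-coding genes. Red bars are called against random lists, and the dashed line is the median protein-coding gene. Lists of 6 other lineages have medians of 0 TPM.

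Growth and biosynthesis genes stood high against random protein-coding lists. Without other cells or another condition, this does not show whether the levels are particular to Ramos cells. All 30 ribosome biogenesis genes passed 1 CPM in both libraries, with the nucleolar proteins NPM1 at 1021 and NCL at 721 TPM and PPAN, a gene with same-strand overlap, at 23.2 TPM. All 27 nucleotide and one-carbon metabolism genes passed, from the polyamine enzyme ODC1 at 923 TPM and the purine enzyme PAICS at 390.1 TPM to ADSL at 18.0 TPM. All 29 cell cycle genes passed, led by MYBL2 at 981 TPM and the replication clamp PCNA at 861 TPM, with CCNE1 at 50.7 TPM. In glycolysis and transport 22 of 24 genes passed, with GAPDH at 3207, ENO1 at 1109 and SLC16A3 at 9.33 TPM. Among translation factors EEF2 reached 3004 TPM, EEF1A1 1222 TPM and EIF3C 3.04 TPM. Reads placed at several sites were not counted, so a low value such as that of EIF3C may understate the level. Cholesterol synthesis ran from SREBF2 at 303 and HMGCS1 at 285 TPM to CYP51A1 at 3.97 TPM, a gene with same-strand overlap. Each of these 6 lists lay at percentile 100 (adjusted p = 0.000533).

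Mitochondrially encoded genes had the highest list median, 6861 TPM, with MT-CO3 at 13784, MT-CO1 at 10804 and MT-ATP8 at 2556 TPM. Replication-dependent histones, whose transcripts lack poly(A) tails, had a median of 737 TPM, with HIST1H1B at 5078, HIST1H3B at 4930 and HIST1H4E at 311 TPM. Ribosomal proteins had a median of 492 TPM, with RPS21 at 1932, RPL13A at 1755 and RPL36A at 21.6 TPM. Long non-coding and snoRNA host genes were led by MALAT1 at 2644 and SNHG5 at 345 TPM, with MINCR at 14.3 TPM. All of these lists lay at percentile 100 (adjusted p = 0.000533). Amino acid and unfolded protein stress genes, led by ATF4 at 629 TPM and the chaperone HSPA5 at 492 TPM with SLC7A11 at 15.8 TPM, lay at percentile 99.84 (adjusted p = 0.00777) and lost the call in CPM and against genes with at least 10 counts. In all, 14 of 32 lists were called above random lists and 0 below.

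The other lists were not called. Near MYC on 8q24, CASC11 had 276 ± 11.2 TPM, PVT1 44.4 ± 3.31 TPM and PCAT1 0.307 TPM (SD, n = 2), and the list lay at percentile 97.3 (adjusted p = 0.117) but was called in CPM and by the mean of members. The apoptosis regulators BIK at 373 and MCL1 at 294 TPM led the BCL2 family, with BBC3 at 4.01 TPM. CDK inhibitors were led by CDKN2C at 75.9 and CDKN2A at 56.2 TPM, with CDKN1B at 11.9 TPM. RRM2B at 204 and MDM2 at 182 TPM led the p53 targets. BIRC3 at 154 and NFKBIA at 89.0 TPM led the NF-kB targets, with CD44 at 0.983 TPM. BTG2 at 327 and IER2 at 66.6 TPM led the immediate early genes, with ATF3 at 1.44 TPM. OAS1 at 30.5 and OAS2 at 23.7 TPM led the interferon-stimulated genes, with IFIT2 at 1.26 TPM, and BNIP3 at 94.6 and P4HA1 at 89.4 TPM led the hypoxia genes, with ANKRD37 at 11.6 TPM. Among structural RNAs RN7SL2 had 7178 TPM and SCARNA7 363 TPM, while 6 of 11 members had no counts.

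Ribosomal protein and histone transcripts were lower in replicate 2 than in replicate 1. Of 79 ribosomal protein genes 3 were higher in replicate 2, the median log2 ratio was -0.12, and 36 were called higher in replicate 1 (62 in either direction adjusted over the list alone). RPS21 had a log2 ratio of -0.21 ± 0.03 (counting SE) and RPL13A of -0.16 ± 0.02. Of 23 histone genes 0 were higher in replicate 2, the median was -0.13, and 3 were called higher in replicate 1 (11 in either direction adjusted over the list alone), among them HIST1H3B at -0.13 ± 0.03. Both lists lay at percentile 0 of lists matched on expression (adjusted p = 0.00230). Mitochondrially encoded genes had a median of -0.08, with 8 of 13 called higher in replicate 1 (12 in either direction adjusted over the list alone), and the list was not called (adjusted p = 0.0561). Pan-B-cell and glycolysis genes had medians of -0.07 and -0.06 with the same adjusted p. After a correction for GC content, chosen after the data were seen, those medians were -0.022 and -0.0049 (adjusted p = 0.486 and 0.915). The histone median was then -0.070 and that of ribosomal proteins -0.11, both still called, and mitochondrial genes were called at -0.09 (adjusted p = 0.00307). Ribosomal proteins took 3.74% of counts (Clopper-Pearson 95% interval 3.72% to 3.75%) in replicate 1 and 3.46% (3.44% to 3.47%) in replicate 2. Across 10013 other genes the log2 ratio fell with GC content (Spearman rho -0.399 across genes, which are not independent replicates). In 5 bins of genes, the median went from 0.07 in the bin lowest in GC to -0.08 in the highest. The ratio of these genes also rose with transcript length, taken as the median of a gene's annotated transcripts (Spearman rho 0.140). Its median was -0.02 in the bin of shortest transcripts and 0.03 in the bin of longest.

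**Figure D3:**
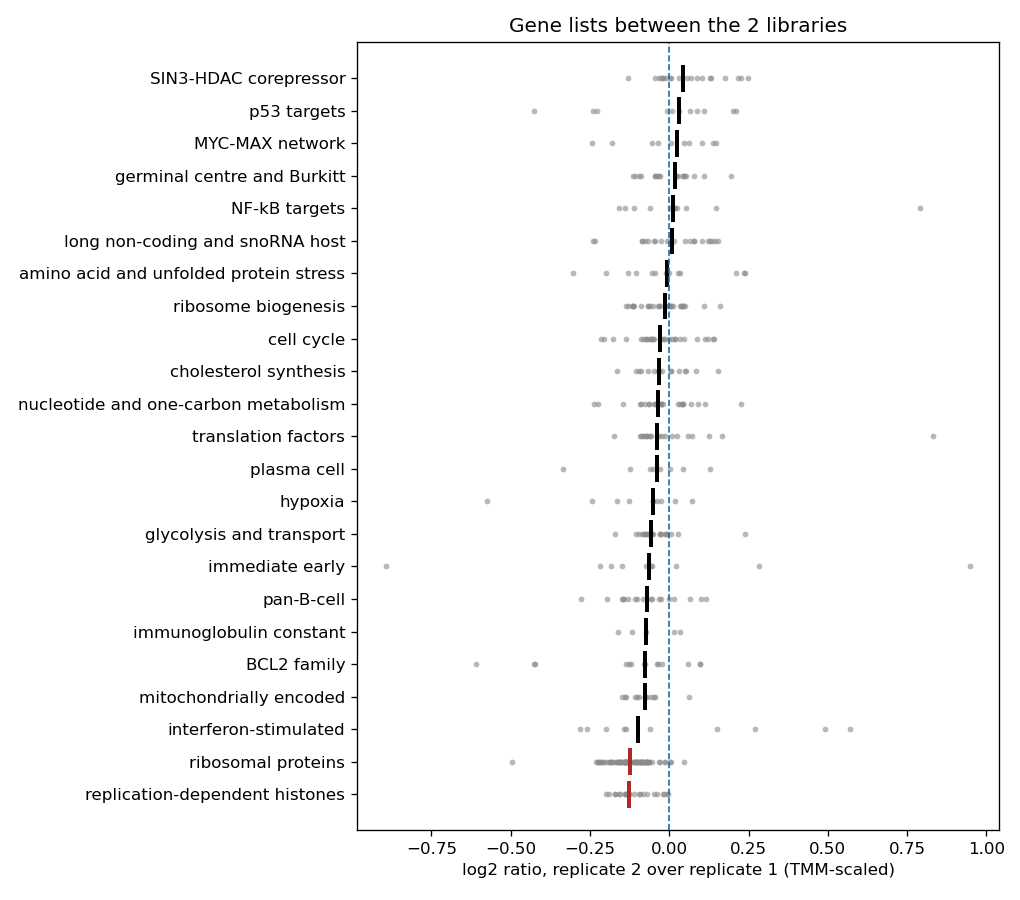
Grey points are list members with at least 20 counts in total and thick bars are list medians, as the TMM-scaled log2 ratio of replicate 2 over replicate 1, for 23 lists. Red bars are called: ribosomal proteins at a median of -0.12 and histones at -0.13.

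Gene by gene, 156 of 15084 genes differed between the libraries, 107 higher in replicate 1 and 49 higher in replicate 2. Ratios were ranked only among called genes with at least 100 counts in total. The largest toward replicate 1 were the spliceosomal RNA RNU4-2 (log2 -1.30 ± 0.30, counting SE, exact binomial adjusted p = 0.00113) and SLC25A14 (-1.14 ± 0.28). The small nucleolar RNAs SNORA71A (-0.90 ± 0.23) and SNORD3A (-0.48 ± 0.09) and the respiratory chain gene NDUFB7 (-0.55 ± 0.13) came next. Toward replicate 2 the largest ratios in this set were AC010168.2 (0.68 ± 0.19), AMER1 (0.59 ± 0.15) and NR2F6 (0.50 ± 0.13). C2orf69 (0.44 ± 0.12) and the anaphase-promoting complex gene ANAPC4 (0.35 ± 0.08) came next. MALAT1 was higher in replicate 2 by 0.10 ± 0.01. At an unadjusted p of 0.05 the split was 764 and 695. After the correction for GC content 56 genes were called, 48 higher in replicate 1 and 8 higher in replicate 2, and 49 of them were among the 156. In simulated libraries with a variation of 3.26%, estimated from these same libraries, 224 unchanged genes were called beside the genes set to change. The test compares these libraries, not conditions.

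Across 15084 genes the libraries correlated with Pearson r = 0.995 and Spearman rho = 0.993 in log2(CPM + 1). The robust SD of the log2 ratio was 0.116 (bootstrap 95% interval 0.114 to 0.119) over 8650 genes with at least 100 counts in both libraries, against a median counting SD of 0.0938. After the correction for GC content the robust SD was 0.0965. Chi-square per degree of freedom was 1.60, so the libraries differed by more than sampling noise. The mean per gene rose with total counts, from 1.06 in the lowest count bin to 6.67 in the highest, which held 561 genes. In that highest bin the robust SD was 0.0801, against a median counting SD of 0.0337. Numbers of called genes in lists of abundant genes, such as ribosomal proteins and mitochondrial genes, therefore depend on count as well as on list. The excess over sampling noise does not tell separate cultures from technical repeats, and the libraries were counted as 2 samples as the labels list them.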

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

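Both tests of the HIV-1 reads were chosen after the counts were seen. The viral row named HIV-1, outside the gene counts, held 1083 reads in replicate 1 and 860 in replicate 2, above the 3 counts that a count of 0 allows. The highest other viral row held at most 0.814% as many reads, which leaves open host reads that align to this sequence in particular. Transcripts of the lentiviral constructs, which share sequence with that virus, are a candidate source as a hypothesis. The libraries carried the reads at rates that an exact binomial test did not separate (p = 0.453), and without a library of untransduced cells the vector and host reads cannot be told apart. No biological explanation was tested.

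The row named HCV-2 held 2 reads in replicate 1 and 7 in replicate 2, the latter above the 3 counts that a count of 0 allows. That limit covers counting error and not stray alignments, which were not tested. So few reads therefore do not show that sequence of this virus was present. Decoy contigs held 2303 reads in replicate 1 and 1838 in replicate 2.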

How the results depend on the processing

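Leaving out either replicate kept the direction and the side of the threshold for all 32 list levels and all 7 lineage comparisons. Another scaling moves every gene by 1 constant, so it cannot change the percentile of a list shift, but the median of the long non-coding and snoRNA host list turned from 0.0088 to -0.0019 with DESeq2 size factors. The robust SD was 0.160 at 10 counts in both libraries, 0.0800 at 1000, and 0.0965 after the GC correction, which was chosen after the data were seen. The count of 156 genes became 9 at a minimum fold of 1.5, 6 at 2 and 56 after the GC correction. That correction moved the shift of immunoglobulin constant genes to percentile 58.3 and of stress genes to 54.0, both reversed, and mitochondrial genes to 0.01, now called. With no count filter the percentiles of the NF-kB, immunoglobulin constant and interferon shifts crossed to 24.6, 60.2 and 84.1. There, members with 0 counts in both libraries take a constant log2 ratio of 0.28 from the pseudocount, so these percentiles do not measure a shift, and the NF-kB median stayed positive (0.013 and 0.018). A background of at least 10 counts in both libraries tests fewer genes and also drops list members below that count. There the levels of MYC-MAX (43.2), BCL2 family (49.1), immunoglobulin constant (100), 8q24 (16.6), p53 (46.5) and hypoxia (43.7) lists reversed. SIN3-HDAC (91.5) and stress (91.6), which kept all members, lost their calls. Plasma cell (99.99) and interferon (0.67, below) gained them, as did the immunoglobulin constant list (adjusted p = 0.000417 against random lists). Of 16 immunoglobulin constant genes 5 remained, and their median log2(TPM + 1) moved from 0.284 to 9.55. Of 11 plasma cell genes 8 remained, and the median moved from 5.33 to 7.78. Too few members remained there in 7 lists to give a value. By the mean of members, plasma cell (99.9), BCL2 family (99.5) and 8q24 (99.1) were called above and T cell (0.07), NK cell (0.07), myeloid (0), erythroid (0.02), epithelial (0.08) and fibroblast (0) below, while immunoglobulin constant (52.9), structural RNA (99.98, now called, adjusted p = 0.00107) and immediate early (61.0) lists reversed. In CPM, 8q24 (99.94) and hypoxia (99.5) gained calls and stress genes (98.7) lost theirs. The 6 non-mitochondrial genes among the 10 highest took 2.10% of the total without mitochondrial genes. Where list members were dropped, their effect was not separated from that of the smaller background. The cause of the other changes was not tested. No paired analysis was possible because there is 1 group. At this depth a count of 0 allows up to 3 counts, or 0.341 and 0.415 CPM, so a 0 does not exclude levels below that.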

Other observations

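Genes in this paragraph were chosen after their values were seen. Among immunoglobulin variable segments IGLV2-14 had 7203 ± 188 TPM, IGHV4-34 4144 ± 55.5 TPM and IGLV2-23 2812 ± 137 TPM (SD, n = 2), and the lambda segments share sequence, so reads can be split between them. Long non-coding genes outside the lists included EBLN3P at 244 ± 15.6 TPM, GABPB1-AS1 at 81.5 ± 7.58 TPM and FAM30A at 51.9 ± 2.25 TPM. NEAT1, the scaffold of paraspeckles, had 206 ± 16.4 TPM. The mitochondrial ribosomal RNA MT-RNR2 had 418 CPM in replicate 1 and 339 CPM in replicate 2, and MT-RNR1 had 207 and 163 CPM.

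Both tests on the lower ribosomal protein and histone transcripts of replicate 2 were chosen after the shifts were seen. Transcript length stays open as a cause. Medians stayed -0.115 and -0.113 from those of other genes matched on expression and length. Matches for histones were longer than the histones by 0.20 on the log2 scale. Length was the median of a gene's annotated transcripts, which can fall far below its combined exon length. Examples are PABPC1, with 629.5 against 4752 bases, and MALAT1, with 480 against 8829. Genes matched as short may thus have long transcripts, so the test cannot decide. GC content may account for part, since medians stayed -0.111 and -0.0849 from matched genes, whose own medians were -0.01 and -0.04, and the GC correction left -0.11 and -0.070. What else differed between the libraries stays open, and no biological explanation was tested.

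Both tests of the T cell receptor reads were chosen after the counts were seen. The constant regions of T cell receptor genes held 742 and 585 reads, with TRBC2 at 244 ± 8.06 TPM and TRAC at 133 ± 0.103 TPM (SD, n = 2). T cells among the Ramos cells are argued against, since CD3D, CD3E, CD3G and CD2 together held 0.226% as many reads. Transcripts of unrearranged constant regions may be the source, as a hypothesis, since variable segments held 0.678% as many reads, or 9 against 1327, while immunoglobulin variable segments held 26235 against 66109.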
